A study of Mus musculus with 2 samples.

How the data were processed

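Chromatin accessibility was measured by ATAC-seq in the facial prominence of mouse embryos at 13.5 days, in 1 group of 2 biological replicates. In ATAC-seq a transposase inserts sequencing adapters into DNA that is not wrapped tightly in nucleosomes, so insertions collect at active promoters, enhancers and insulators. Per the labels, the tissue was excised from healthy embryos of the strain B6NCrl, male and female embryos were pooled, DNA was cut by Nextera tagmentation, and the libraries held fragments of 200 to 750 bp. No other tissue, age or treatment was analysed here, so the libraries allowed no test between groups.

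The authors' peak lists were the starting point. They comprised 12 lists, 3 for each replicate and 6 for both replicates together, all on mouse build mm10 per the labels. The aligner, the peak caller, their versions and the read filters were not given in the sources used here, and neither was any shift of reads for the transposase. Each deposited list gave intervals with a summit. The score of a peak, per the deposited values, stopped at 540 in the lists thresholded on the irreproducible discovery rate (IDR), which corresponds to an IDR of 0.05, and was capped at 1000. The signal value of each peak was the authors' own peak strength, on a scale that the sources used here did not state, and was used only to rank, match and describe peaks within a list. The −log10 p of each peak was taken as deposited and was used only to describe peaks that were in the ranked but not in the thresholded lists. A further 8 columns of per-replicate values in the ranked list between replicates were not used. The files held no read counts, so the depth of each library is unknown, and the intervals below cover only the counting of peaks, genes or windows.

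The list thresholded on IDR between pseudoreplicates of the pooled reads was the main list and is called the series list. A conservative list came from IDR between the true replicates, and a looser replicated list held pooled peaks found in both replicates. Several summits often shared 1 interval, so each distinct interval was counted once, at its strongest summit by signal. Intervals were placed against assembly GRCm38, the same build as mm10, and its GENCODE annotation of 21938 protein-coding genes. Of these, 21853 had a protein-coding transcript, with 54361 transcription start sites (TSSs) in all. All peaks on chromosomes lay within the assembly's chromosome lengths. A promoter peak lay within 500 bp of a TSS of a protein-coding gene and a distal peak lay over 1000 bp from all of them. TSSs of noncoding genes therefore did not exclude a peak from the distal class, and an alternative with all gene types was computed. Each distal peak was assigned to the gene of its nearest TSS, which names a neighbour and not a target.

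Overlap between replicates was counted from 1 bp upward and compared with 100 random placements of the same widths on the same chromosomes, outside runs of unknown bases of 1000 bp or more. The 14 gene lists covered facial mesenchyme regulators, clefting and signalling genes, cartilage and bone, facial epithelium, skeletal muscle, endothelium, erythroid cells, myeloid cells, neurons, Schwann cells and melanocytes, posterior Hox genes, regulators of other organs, terminal genes of adult organs, and housekeeping genes. Of 355 entries, 354 matched the annotation. A few genes stood in 2 lists, for example Dlx5, Mef2c, Pitx2 and Tfrc, and were left out of tests between the lists that shared them. Promoter shares were compared with all other protein-coding genes by Fisher's exact test, two-sided. Distal peaks per gene were compared with 10000 random lists of the same size, matched on the length of the domain in which a gene's TSS is the nearest one, in 10 classes of length, which gives a two-sided permutation p of at least 0.00020. Differences between lists were tested by Fisher's exact test for promoters and by 100000 permutations of the list labels for distal peaks, with 5000 bootstraps for intervals. Consensus sequences of 28 transcription factor families were searched on both strands within 100 bp of distal summits. They were compared with windows of 201 bp outside all peaks, matched on chromosome and on GC content in steps of 2 percentage points, by Fisher's exact test. P-values were adjusted by the Benjamini-Hochberg method within their family with a threshold of 0.05, and shares have Wilson 95% intervals. Genes, peaks and windows are not biological replicates, so these p-values describe the lists from these libraries.

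The gene lists, the motifs, the tests of lists and of motifs in distal peaks and their alternative settings were fixed before the data were examined, except for 4 settings added later: lists without their top gene, each summit counted, TSSs of all gene types, and single-copy distal peaks. The promoter motif search and the tests of copies, of mitochondrial matches, of looser-list promoters that passed IDR and of motif spacing were also added later. The rule for named items was fixed before the data were examined. It took from each gene list the 3 members with the most distal peaks and up to 5 members without a promoter peak (the first 3 by symbol where there were more), then the 10 genes with the most distal peaks, the 10 strongest distal and promoter peaks, and the motifs with the 5 highest and 3 lowest odds ratios. Other genes and motifs named as examples were chosen after their values were seen. The alternative settings changed the peak list, the replicate, the strength of the peaks, the promoter window, the definition of overlap, the matching of random lists and the background of the motif search.

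The steps were tested on simulated data. For replicate overlap, the recovered share differed from the simulated one by 0.16 percentage points on average over 8491 peaks. For distal peaks, lists of 30 genes out of 21853 had an unadjusted permutation p under 0.05 in 5% of 40 simulations with no change. They did so in 32.5% at a fold of 2 and in 97.5% at a fold of 4. For promoters, lists of 30 genes had an unadjusted p under 0.05 in Fisher's exact test in 6% of 200 simulations at an open share of 48%. The share was 95% at 80% open and 98.5% at 15% open. The real lists were called on adjusted p-values, which the simulations did not use. For motifs, a motif planted in 5% of 3000 windows was called more frequent in 100% of 10 runs, and an unplanted one in 0% of 10. Only the planted share was varied in these runs. They therefore cannot show how far the calls in real sequence depend on base composition or on the choice of background. Copies of distal peaks elsewhere in the assembly were searched with minimap2 2.31 at 95% identity over 80% of the peak, and matches to the mitochondrial genome with blastn 2.17.0. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1.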

Results

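ATAC-seq of the mouse embryonic facial prominence, the tissue that forms the upper and lower jaws, nose and palate, was available for 1 group of 2 biological replicates at 13.5 days. The tissue mixes mesenchyme of neural crest origin with surface epithelium, muscle precursors, vessels, blood, nerve and early cartilage and bone, so a peak can come from any of them. The series list held 13366 accessible intervals covering 11.3 Mb, with a median width of 839 bp. The separate list of replicate 1 held 8491 intervals covering 6.71 Mb and that of replicate 2 held 9454 covering 7.52 Mb. Read depth was unknown, because the values were peak scores and not counts. A promoter without a peak was therefore not detected as open at this depth and threshold, which does not show that it was closed.

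The first question was which promoters were accessible in the developing face. A peak lay within 500 bp of a TSS for 10477 of 21853 protein-coding genes (47.9%, Wilson 95% interval 47.3 to 48.6). Genes used by all cells stood above this level. Of 30 housekeeping genes, 27 had a promoter peak (90%), among them the cytoskeletal gene Actb and the glycolytic gene Gapdh. Psmb4 of the proteasome, Rps18 of the ribosome and the ubiquitin gene Ubc had none. The adjusted p of the housekeeping list was 1.3e-05 in Fisher's exact test against all other genes, and of the 14 lists it was the only one that passed the threshold above them.

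Regulators of facial mesenchyme were open at about the rate of all genes. Of 44 such transcription factor genes, 23 had a promoter peak (52.3%, 37.9 to 66.2), with an adjusted p of 0.70 in Fisher's exact test. They included Twist1 and Msx1, which act in cranial neural crest mesenchyme, Alx1, needed for the midface, and Dlx5, which patterns the lower jaw. The Twist1 promoter peak lay on chromosome 12 at 33956931 to 33958154 with a signal of 8.48, and that of Alx1 on chromosome 10 at 103028218 to 103029239 with a signal of 9.05. Both were present in each replicate's own list. Barx1, Dlx2 and Dlx3, homeobox genes of the jaws and teeth, had no promoter peak in the series list. In the looser replicated list, 36 of the 44 genes had a promoter peak (81.8%, against 60.2% of other genes), with an adjusted p of 0.0071 in Fisher's exact test. The direction turned in the stronger 50% of peaks, where the share was 13.6% against 30.9% of other genes (adjusted p 0.022, Fisher's exact test). In each replicate alone it was 29.5%, with adjusted p of 0.60 and 0.25.

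Signalling genes of lip and palate development had 16 of 30 promoters open (53.3%, adjusted p 0.69, Fisher's exact test). Open promoters included those of Fgfr1 and Fgfr2, receptors for fibroblast growth factors, and of Gli2, Gli3 and Ptch1, which carry the hedgehog signal. Bmp2, a bone morphogenetic protein, and Aldh1a2 and Aldh1a3, which make retinoic acid, had none. In the looser list 26 of the 30 genes had a promoter peak (86.7%), with an adjusted p of 0.0067 in Fisher's exact test, and in replicate 1 alone 10 had one (33.3%, adjusted p 1). Genes of cartilage and bone had 7 of 20 promoters open (35%, adjusted p 0.38), and 3 of 20 (15%) in replicates 1 and 2 alone, with adjusted p of 0.087 and 0.051 in Fisher's exact test. These included Sox9, the master regulator of cartilage, and the collagen genes Col1a1, Col1a2 and Col2a1, while Acan and Alpl, which serve cartilage matrix and mineralisation, and the osteocalcin gene Bglap had none. Epithelial genes had 8 of 24 open (33.3%, adjusted p 0.34), including Irf6, a clefting gene of the oral epithelium. Cdh1, Cldn4 and Cldn7, which join epithelial cells, had no promoter peak. In the lists of single replicates the epithelial share was 12.5% for replicate 1, with an adjusted p of 0.028 in Fisher's exact test, and 16.7% for replicate 2, with an adjusted p of 0.034.

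Promoters of genes used by other cell types and other parts of the body were open less often than those of other genes in 7 lists. None of 27 Hox genes of paralog groups 5 to 13, here called posterior, had a promoter peak (0%, upper limit 12.5%), with an adjusted p of 1.7e-07 in Fisher's exact test. These genes pattern the trunk and limbs and included Hoxa10, Hoxa11 and Hoxa13. They lie in clusters, so the test and the limit treat linked promoters as independent. Of 39 genes of differentiated adult organs, 1 had a promoter peak (2.56%, adjusted p 8.8e-09, Fisher's exact test). That gene was Mbp, of the myelin sheath, while the albumin gene Alb, the intestinal phosphatase gene Alpi and the apolipoprotein gene Apoa1 had none. Of 40 regulators of other organs, 6 had one (15%, adjusted p 6.9e-05). The intestinal regulators Cdx1 and Cdx2 and the neural homeobox gene Barhl1 were not among them.

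The minor cell types of the face followed the same direction. None of 16 endothelial genes had a promoter peak (0%, upper limit 19.4%), with an adjusted p of 0.00010 in Fisher's exact test. Cdh5, the cadherin of vessels, Cldn5 and Egfl7 were among the 16. Of 18 skeletal muscle genes 1 had a peak (5.56%, adjusted p 0.00041), the cadherin gene Cdh15, and the actin genes Acta1 and Actc1 and the acetylcholine receptor gene Chrna1 had none. Of 16 myeloid genes 1 had a peak (6.25%, adjusted p 0.0012), Cebpa, and the macrophage genes Adgre1, Aif1 and C1qa had none. Of 18 erythroid genes 2 had one (11.1%, adjusted p 0.0027), the erythropoietin receptor gene Epor and the transferrin receptor gene Tfrc. The haem synthesis gene Alas2, Epb42 and Ermap had none. The endothelial and muscle lists lost their calls in the looser list, at 43.8% and 50% open, with adjusted p of 0.32 and 0.63 in Fisher's exact test. Neuronal genes (8 of 20, 40%, adjusted p 0.65) and genes of Schwann cells and melanocytes (5 of 12, 41.7%, adjusted p 0.78) did not differ from other genes by Fisher's exact test, and in each replicate alone their shares were 20% and 25%. Ascl1, Elavl3 and Emx2 among the neuronal genes, and Dct, Erbb3 and Fabp7 among the glial and pigment genes, had no promoter peak.

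The difference between the face list and other lists was tested itself. Facial mesenchyme regulators were open more often than regulators of other organs (52.3% against 15%, adjusted p 0.0012, Fisher's exact test). The same held against posterior Hox genes (adjusted p 5.7e-06, Fisher's exact test), whose clustered promoters are not independent. The facial mesenchyme regulators were also open more often than the muscle, endothelial, myeloid and erythroid genes, with adjusted p of 0.0012, 0.00065, 0.0020 and 0.0060 in Fisher's exact test, and less often than housekeeping genes (0.0018). They did not differ by this test from the clefting, cartilage and bone, epithelial, neuronal, or glial and pigment lists. Between replicates, the share of all genes with a promoter peak was 37.4% ± 2.75 (SD, n = 2), and each replicate alone had fewer peaks than the series list. Promoters of 7111 genes were open in both replicates and those of 2111 in 1 replicate.

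**Figure D1:**
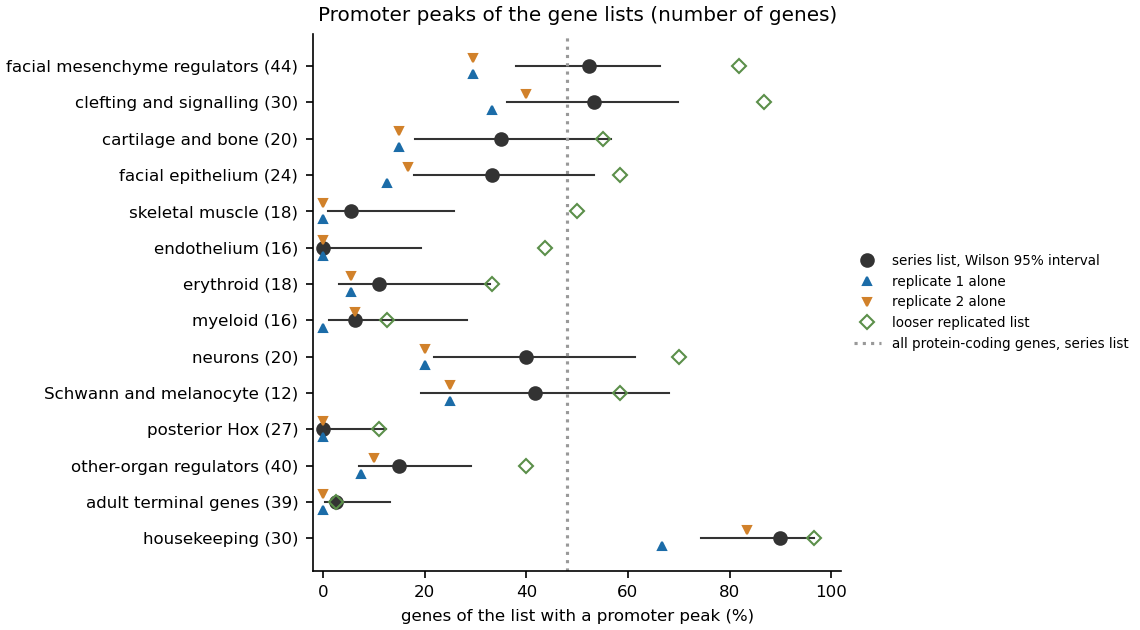
Share of the genes of each list with a promoter peak, in percent, for the series list (circles with Wilson 95% intervals), each replicate alone (triangles) and the looser replicated list (diamonds), with the share of all protein-coding genes as a dotted line. Posterior Hox and endothelial genes sit at 0% and housekeeping genes at 90% in the series list, and facial mesenchyme regulators move from 52.3% to 81.8% in the looser list.

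Distal peaks were then assigned to the nearest gene, to ask which gene groups lay beside open distal elements. Genes of cartilage and bone had the most for their setting, with 25 distal peaks beside 20 genes, 14 of which had at least 1. Their mean of 1.25 peaks per gene was 5.32 times that of random lists matched on domain length. The permutation p was 0.00020, the smallest the random lists can give, and the adjusted p was 0.0028. Col1a1, which encodes the main collagen of bone, had 4 such peaks in the series list and 3 in the list of each replicate. The strongest of the 4 lay on chromosome 11 at 94882584 to 94883347, 53360 bp from the TSS, while the Col1a1 promoter peak had a signal of 2.88, near the bottom of the list. Sox6, a partner of Sox9 in cartilage, and Mef2c, which drives chondrocyte hypertrophy and also muscle and neural crest genes, had 4 each and no promoter peak. The strongest near Sox6 lay on chromosome 7 at 115453191 to 115453936 with a signal of 8.79, and that near Mef2c on chromosome 13 at 83744804 to 83745635 with a signal of 8.10. Acan, Alpl and Bglap each had 1. The ratio of the list to random lists was 3.36 in the looser list (permutation, adjusted p 0.0014). In replicates 1 and 2 alone it was 5.99 and 6.10 (permutation, adjusted p 0.017 and 0.0028). In the stronger 50% of peaks, which left 3 beside the list, the ratio was 3.20 and missed the threshold (permutation, adjusted p 0.97).

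Clefting and signalling genes had 29 distal peaks beside 30 genes, 12 of which had at least 1, which was 2.88 times the random mean (permutation, adjusted p 0.0084). Gas1, a co-receptor for hedgehog, led with 5, and Bmp7 and Ednra, the receptor that carries endothelin signals to the lower jaw, had 3 each. In each replicate's own list Gas1 had 2, Bmp7 had 1 and Ednra had 0. Bmp7 had no promoter peak. The 5 peaks around Gas1 on chromosome 13 ran from 60099716 to 60365602. Of these, 2 lay in the noncoding gene A530065N20Rik, 1 in an intron and 1 in an exon, and 3 lay between genes. The farthest, at 60364891 to 60365602, was 187847 bp from the TSS and had a signal of 8.89, against 8.74 for the promoter peak at 60176648 to 60177883. The call depended on few peaks. With the 10 peaks of replicate 1 alone the ratio was 2.61 and the adjusted p 0.38, with replicate 2 alone it was 3.75 and 0.0042, and without Gas1 it was 2.49 and 0.078 (permutation tests).

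**Figure D2:**
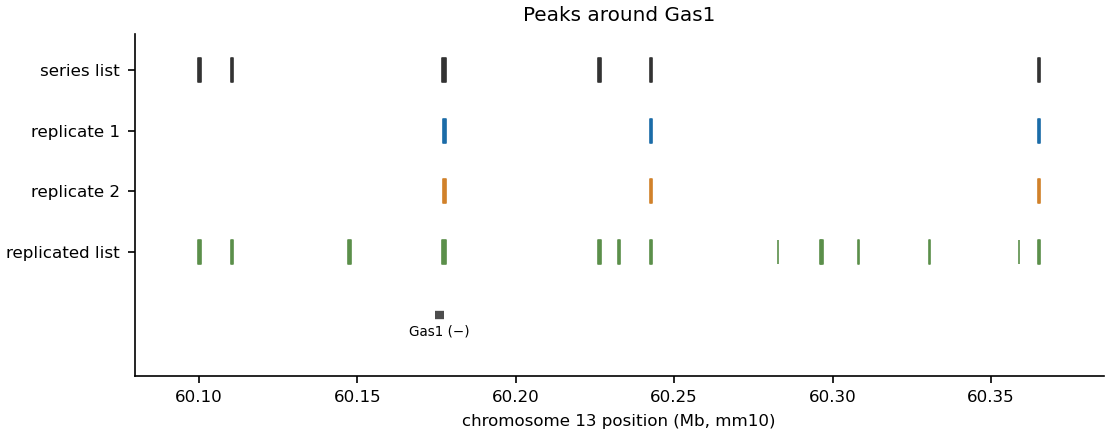
Accessible intervals around Gas1 on chromosome 13 (mm10, position in Mb) in the series list, each replicate's own list and the looser replicated list, with Gas1 as the only protein-coding gene in view. Besides the promoter, 2 distal intervals appear in both replicates, the farther of them at 60364891 to 60365602, and narrow intervals are drawn with a minimal width.

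Facial mesenchyme regulators had 20 distal peaks beside 44 genes, 13 of which had at least 1. Meis1 and Nr2f1, homeobox and nuclear receptor genes of the early face, had 3 each, and Msx1 had 2. In each replicate's own list Meis1 had 1, and Nr2f1 and Msx1 had 0. The list had 1.53 times the random mean, with an adjusted p of 0.68 (permutation), and 0.596 and 0.757 times it in replicates 1 and 2 alone. In the looser list it had 161 peaks, 1.91 times the random mean (permutation, adjusted p 0.0019). Against the cartilage and bone list the observed peaks per expected peak were lower by 6.71 on average (95% bootstrap interval of the difference −11.4 to −2.62, permutation, adjusted p 0.0017). Of the differences from the other lists, only that from the posterior Hox list passed the threshold (1.53 higher, 0.762 to 2.38, permutation, adjusted p 0.032). The Hox list had 0 peaks where matched random lists held only 0.0411 per gene, which is too few for this test to decide.

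None of the other lists passed the threshold against random lists. A fold of 2 was called in only 32.5% of simulated lists of 30 genes (unadjusted permutation p under 0.05), so such differences may have been missed. For most of these lists the central 95% of random lists reached down to 0 peaks, so that no count could be called low. The epithelial list had 9 distal peaks, 2.35 times the random mean (permutation, adjusted p 0.45), with 3 near Grhl2, a regulator of epithelial junctions, and 1 each near Epcam and the desmosome gene Dsp. In replicates 1 and 2 alone it had 1.29 and 1.81 times the random mean, with 0 peaks near Grhl2 in either. The epithelial list passed the threshold when peaks within 100 kb were counted, at 2.60 times the random mean (permutation, adjusted p 0.013). Neuronal genes had 10, 1.61 times the random mean, with 2 each at the synaptic gene Snap25 and the microtubule gene Stmn2 and 1 each at Ascl1 and Emx2. In replicate 1 alone they had 1, 0.419 times the random mean, and in replicate 2 alone 4, 1.61 times it. Muscle genes had 5, of which 4 were those of Mef2c and 1 lay near Pax7, the gene of muscle stem cells. In the looser list the muscle genes stood 2.56 times above random lists (permutation, adjusted p 0.013). Endothelial genes had 2, at Cdh5 and Sox17, and myeloid genes had 2, both near Ptprc, the pan-leukocyte gene. Genes of Schwann cells and melanocytes had 1, near Ets1, and erythroid and posterior Hox genes had 0. Regulators of other organs had 7, including 2 each near Gata6 and Pax8 and 1 near Gata3. Adult terminal genes had 3, of which 2 were near the sperm chromatin gene Tnp1 and 1 near Apoa1. Housekeeping genes had 5, with 1 each near Eef1a1, Gpi1, Ppia, Ubc and Ywhaz. Over these lists the ratios ran from 0 to 2.35 and the adjusted permutation p from 0.45 to 1. Within 100 kb, where neighbouring genes share peaks, the posterior Hox genes had 0 against a random mean of 0.604 per gene (permutation, adjusted p 0.0028). These genes lie in clusters and share their windows, while the random lists draw scattered genes, so that the test treats linked counts as independent.

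**Figure D3:**
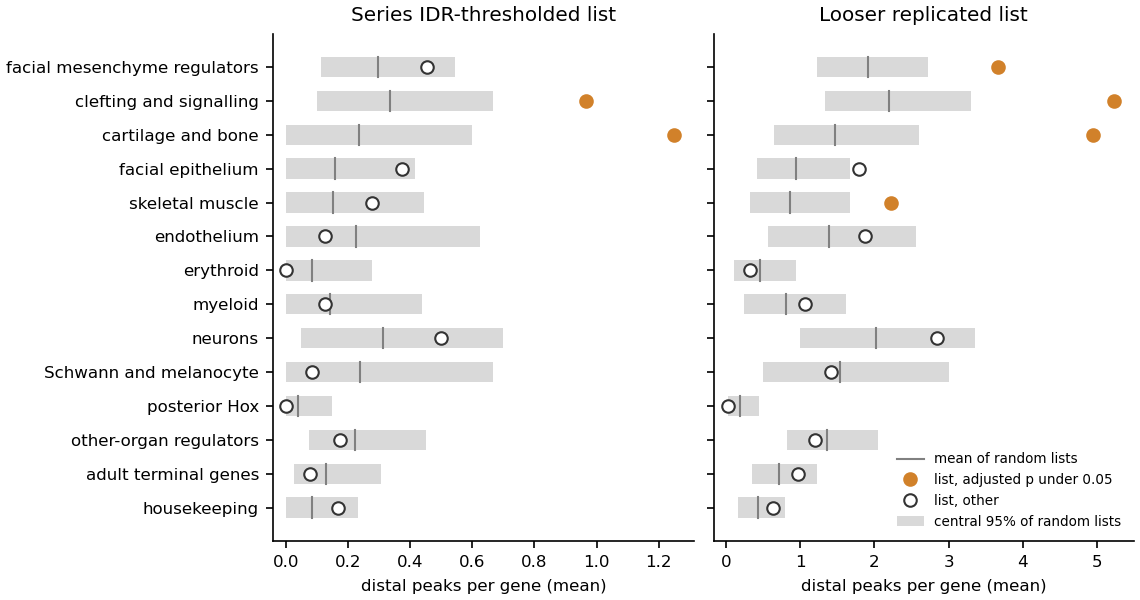
Mean number of distal peaks per gene for each list in the series list (left) and the looser replicated list (right), with the mean and the central 95% of random lists matched on domain length in grey. Filled points mark an adjusted p under 0.05, which in the series list are cartilage and bone at 1.25 and the clefting list at 0.967 peaks per gene.

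Across the genome 2417 genes (11.1%) had at least 1 distal peak and 31 had 5 or more. The most lay nearest to Sfi1, a centrosome gene on chromosome 11, with 14, and to Scaf8, an RNA-processing gene on chromosome 17, with 9. Both genes border the start of their chromosome's sequence, so that domains of 3198 kb for Sfi1 and 3221 kb for Scaf8 were assigned to them. The 14 peaks lay at most 86866 bp from a Sfi1 TSS, and the 9 at most 94404 bp from a Scaf8 TSS. The distant parts of these long domains therefore added none of them. Most of the 14 had a signal of at most 4.04, within the weakest 10% of series peaks, which reached up to 4.21. Some of the Sfi1 peaks lay in the gene Pisd-ps1 and some of the Scaf8 peaks in Pisd-ps2. Copies of these peaks elsewhere in the assembly were not counted gene by gene. Next came Sorl1 and Trio, a sorting receptor and a guanine exchange factor for neurite growth, with 7 each. Nfe2l3, 1700001O22Rik, 2010111I01Rik and Gm21860 also had 7. Nfib, a nuclear factor I gene, Smad7, an inhibitor of TGF-beta signals, and Acot11, Chd2, Eapp, Gm26897 and Gse1 had 6 each. All these counts were lower in the lists of replicates 1 and 2. Sfi1 had 7 and 5 there, Trio 2 and 3, 1700001O22Rik 1 and 3, and Nfib 3 and 1.

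The sequence of distal peaks was searched for the binding motifs of 28 transcription factor families. The insulator factor CTCF was matched near 3.64% of distal summits against 0.298% of GC-matched windows, with an odds ratio of 12.04 (95% interval 6.19 to 23.4, adjusted p 1.9e-22, Fisher's exact test). NF-Y, which binds CCAAT boxes, was matched in 7.58% against 1.69% (odds ratio 4.74, 3.49 to 6.44, adjusted p 7.6e-28, Fisher's exact test). SP and KLF motifs were 4.12 times as frequent by odds ratio (2.898 to 5.868, adjusted p 2.6e-17), the octamer of POU factors 3.68 times (1.964 to 6.896, adjusted p 4.8e-05) and ETS motifs 3.38 times (1.74 to 6.54, adjusted p 0.00047, Fisher's exact test). TEAD motifs stood at 2.23 (1.72 to 2.89), RUNX motifs, bound by Runx2 in osteoblasts, at 2.12 (1.63 to 2.75) and the TAATTA core of homeodomain factors such as Msx and Dlx at 2.07 (1.41 to 3.03). SOX motifs stood at 1.77, forkhead motifs at 1.63 and AP-1 at 1.59. The SOX motif kept its call only in replicate 1 alone (2.29, adjusted p 0.012, Fisher's exact test), and under all other alternatives its ratio ran from 0.877 to 1.70. AP-1 lost its call in each replicate alone, at 1.15 in replicate 1 (adjusted p 0.81) and 0.9503 in replicate 2 (adjusted p 1, Fisher's exact tests). TAATTA lost it in replicate 1 alone (1.55, adjusted p 0.34), within 50 bp of the summit (1.23, adjusted p 0.71) and among single-copy peaks (1.48, adjusted p 0.079, Fisher's exact tests). Against the reversed consensus in the same windows ETS lost its call (1.48, adjusted p 0.17) and so did the forkhead motif (1.31), which also lost it in replicate 1 alone (1.22). In the stronger 50% of peaks only the CTCF, NF-Y, SP and KLF, ETS, TEAD and TAATTA motifs passed the threshold as more frequent, and GATA did so as less frequent (0.197).

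In all, 17 of the 28 motifs were more frequent in the 3020 matched distal peaks and 0 were less frequent, with 0 also at an unadjusted p under 0.05 (Fisher's exact test). NRF1, a promoter factor, was found in 14 peaks and 1 window (odds ratio 9.71, 1.81 to 52.2, adjusted p 0.0024). Nuclear factor I was found in 7 peaks and 0 windows (adjusted p 0.026, Fisher's exact test). RFX stood in 6 peaks and 1 window, which missed the threshold (adjusted p 0.18, Fisher's exact test). It passed as more frequent in the looser list (odds ratio 45.1) and against the flanks of the same peaks (26.0). The lowest ratios belonged to PBX with HOX (0.523), EBF (0.537) and GATA factors (0.704), none of which passed, at adjusted p of 0.35, 0.19 and 0.26 in Fisher's exact test. For PBX with HOX the direction turned, without a call, within 50 bp of the summit (1.67), against the reversed consensus (1.57) and among single-copy peaks (1.22). GATA passed as less frequent in replicates 1 and 2 alone (0.173 and 0.383, adjusted p 0.00064 and 0.033), in the looser list (0.774, adjusted p 0.0075) and among single-copy peaks (0.513, adjusted p 0.022, Fisher's exact tests). EBF did so in replicate 1 alone (0.171, adjusted p 0.012), in the conservative list (0.374, adjusted p 0.0090) and among single-copy peaks (0.331, adjusted p 0.0039, Fisher's exact tests). The E-box CAGATG, a site of Twist1, stood at 1.28 in the series list, lost its call in the conservative list (1.15, adjusted p 0.095, Fisher's exact test) and fell below 1 in each replicate alone, at 0.951 and 0.975. When the flanks of the same peaks were the background, the TAATTA ratio turned to 0.532, FOX to 0.695 and SOX to 0.877. POU lost its call at 1.31, and GATA (0.395) and PBX with HOX (0.230) passed as less frequent. These flanks were not matched on GC content, and TFAP2 rose against them from 1.24 to 3.31 and SP and KLF from 4.12 to 7.18. A lack of sites can therefore not be told apart from a difference in base composition. CTCF and NF-Y passed the threshold under all alternatives of peak list, replicate, window and background that were run. The CTCF ratio ran from 5.42 in the stronger 50% of peaks to 40.9 in the conservative list, and was 241 against the reversed consensus. The NF-Y ratio was 1.58 in the looser list, 2.79 when peaks within 1000 bp of TSSs of all gene types were left out, and 8.46 and 11.3 in replicates 1 and 2 alone. Nuclear factor I lost its call in the conservative list, within 50 bp of the summit, among single-copy peaks and in each replicate alone, and NRF1 in replicate 1 alone.

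**Figure D4:**
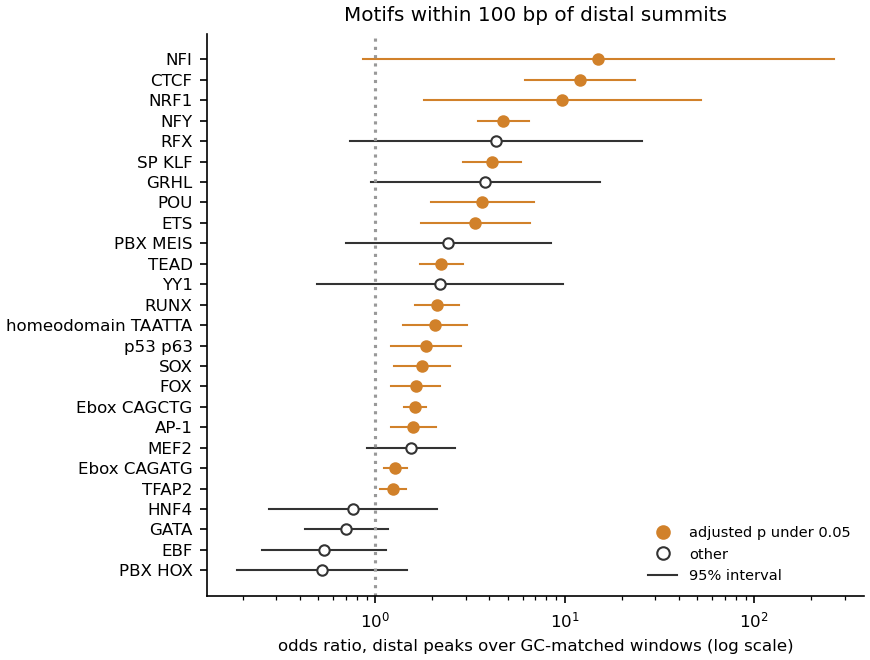
Odds ratio of each motif in distal peaks over GC-matched windows with its 95% interval on a log axis, for motifs with at least 5 matches in peaks and windows together. CTCF at 12.04 and NF-Y at 4.74 have intervals far above 1, and the ratio of nuclear factor I rests on 7 matches against 0, with a correction added to empty cells.

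The accessible intervals lay mainly at promoters. Of 13366 intervals, 9867 (73.8%, 73.1 to 74.6) lay within 500 bp of a TSS, against 2.48% of random placements. A further 3315 (24.8%) were distal, of which 1346 lay in introns, 360 in exons and 1609 between genes. Promoter peaks made up 92.7% of the strongest 10% of peaks and 46.7% of the weakest 10%. In the looser list the promoter share was 40.4%. Chromosome 11 had the most peaks per length (8.44 per Mb), chromosome X had 2.34 per Mb, and the Y chromosome held 8 peaks.

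The 10 strongest peaks of all were distal. The first lay on chromosome X at 143482936 to 143483180 between genes, 35531 bp from Pak3, with a signal of 55.6. Next came peaks on chromosome 2 at 69355470 to 69355735 near Abcb11 (47.3) and at 3964421 to 3964690 near Frmd4a (41.2). The peak on chromosome 10 near Gm5426 (39.8) lay in an intron of a noncoding gene. Peaks near G6pd2, Galc, Tyrp1 and Nxph1 (38.1, 29.2, 29.0 and 23.3) lay at 1765841, 1181919, 831186 and 940307 bp from those genes. Peaks near Cldn34d and Hic2 (25.0 and 23.0) closed the 10. The strongest promoter peak, 12th of all, was that of Kifap3, a kinesin-associated protein gene, on chromosome 1 at 163779305 to 163780031 with a signal of 22.2. Fopnl, Arrdc4, Hibch, Hsd17b7, 2610008E11Rik, Cfdp1, Tmem218, Wbp11 and Rcn2 followed, down to a signal of 18.5. All 20 of these peaks overlapped a peak in each replicate. Of the 10 distal ones, 6 had their summit in a match to the mitochondrial genome and 4 had another copy in the assembly. Overlap between replicates does not tell such sources apart from open chromatin.

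The comparison between samples was that of the 2 replicates. Promoter peaks were shared more than distal ones. Of promoter peaks of replicate 1, 90.7% overlapped a peak of replicate 2 (90.02 to 91.4), and of its distal peaks 67.7% did (65.2 to 70.2). For replicate 2 the shares were 81.1% (80.2 to 81.9) and 62.3% (59.7 to 64.8). Over all peaks, 87.0% of replicate 1 (86.2 to 87.7) and 78.0% of replicate 2 (77.2 to 78.8) overlapped the other, against at most 0.836% in 100 random placements. The overlap fell with strength, from 99.8% of the strongest 10% to 61.4% of the weakest 10% in replicate 1 and from 99.6% to 36.6% in replicate 2. Promoter peaks made up 91.3% and 92.3% of the strongest 10% in replicates 1 and 2, and 64.1% and 63.7% of the weakest 10%. Promoter and distal peaks were not compared at equal strength, so location and strength cannot be told apart here. Of the 1107 and 2080 peaks that did not overlap, 90.06% and 90.05% overlapped the other replicate's looser list. The IDR-thresholded lists of replicates 1 and 2 held 18575 and 20254 summits, a ratio of 1.09. The list from pooled pseudoreplicates held 31516 and that from the true replicates 30087, a ratio of 1.05. The files were distinct, with 21 identical intervals between the replicates.

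**Figure D5:**
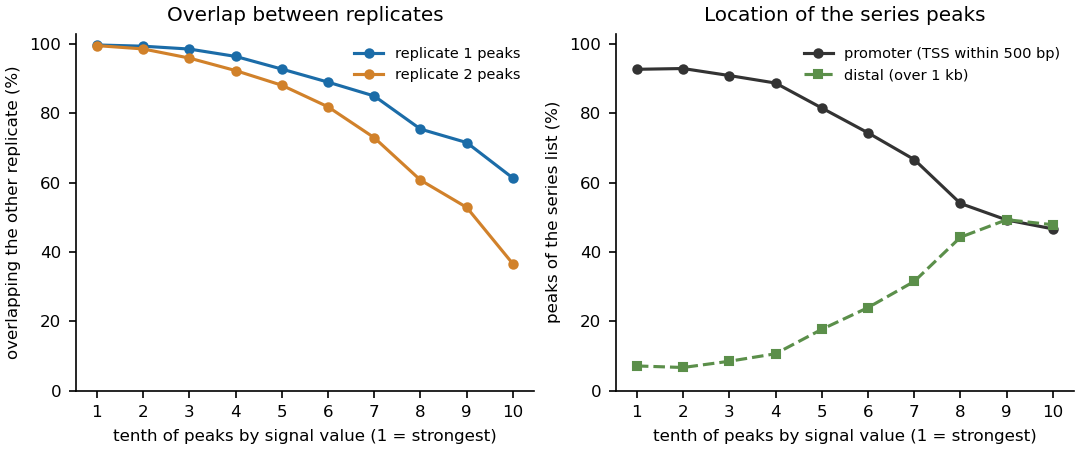
Share of each replicate's peaks that overlap the other replicate (left) and share of series peaks at promoters or distal (right), in percent, in 10 equal classes of signal from strongest to weakest. The overlap falls from 99.8% and 99.6% to 61.4% and 36.6%, and the promoter share falls from 92.7% to 46.7%.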

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

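The counts in the next paragraph were chosen only after the data had been seen.

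Peaks that passed the IDR threshold in a ranked list, and were nonetheless not in the matching thresholded list, drew attention because they are a signal in data that the comparisons did not use. They numbered 329 summits for the pooled pseudoreplicates, in 147 intervals, of which 194 summits lay on chromosomes and 135 on unplaced or unlocalised scaffolds. The other ranked lists held 298 such summits between replicates, 208 in replicate 1 and 212 in replicate 2. The strongest lay on chromosome 1 at 24611587 to 24616171 with a −log10 p of 6937, above the highest value of 6289 in the thresholded list. The median −log10 p of these summits was 64.1, against 18.8 in the thresholded list. No explanation of their absence was tested, and no biological explanation was tested.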

How the results depend on the processing

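Tests without a list's top gene, with each summit counted, with TSSs of all gene types and with single-copy distal peaks were chosen after seeing the data. No paired analysis was possible because the series holds 1 group. The cause of a change was not tested unless it follows from the alternative's construction. Over all results, 491 of 622 alternative values counted as unchanged, and 10 turned direction with a call before or after. Unchanged meant the same side of the threshold for a test, and a fixed margin for a count. For a share it meant the interval of the share or the spread of the replicates. Tests that turned direction with no call before or after also counted as unchanged. Among motifs, 43 of 279 values kept their direction and no longer passed the threshold, 20 kept it and newly passed, and 9 turned direction.

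Counting distinct intervals gave 8491, 9454, 12625 and 13366 peaks for replicate 1, replicate 2, the true replicates and the pooled pseudoreplicates, and an IDR of 0.01 left 10679 and 12552 summits in replicates 1 and 2. Overlap of replicates 1 and 2 was 82.0% and 73.6% at reciprocal 50%, 64.9% and 67.9% for pseudoreplicated lists, 84.2% and 75.6% for the stronger 50% and 83.3% and 82.7% for equal numbers. The promoter share of peaks was 75.6% in the conservative list, 40.4% in the replicated list, 89.4% in the stronger 50%, 71.7% and 76.6% with promoter windows of 100 bp and 2 kb, and 83.3% to 83.9% in single replicates. The distal share was 23.1%, 57.3% and 10.2% in these lists, 23.4% with 2 kb and 15.1% to 15.6% in single replicates. Genes with a promoter peak were 60.2% in the replicated list, 30.8% in the stronger 50%, 44.5% with the gene's 5′ end and 35.4% to 39.3% in single replicates.

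In the replicated list, open promoters passed the threshold for facial mesenchyme (81.8%) and clefting genes (86.7%) and no longer did for muscle (50%) and endothelium (43.8%). In the stronger 50%, facial mesenchyme turned to fewer open promoters than other genes (13.6%) and epithelium passed (8.33%), as it did in single replicates (12.5% to 16.7%). Distal ratios passed in the replicated list for facial mesenchyme (1.91) and muscle (2.56), against unmatched lists for facial mesenchyme (2.99), and within 100 kb for epithelium (2.60) and posterior Hox genes (0). Those no longer past it were cartilage and bone (3.20) and clefting genes (1.55) in the stronger 50%, which left 3 peaks each, and clefting genes without the top gene (2.49) and without replicate 2 (2.61). Without replicate 1 clefting genes passed (3.75).

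More frequent motifs numbered 6 in the stronger 50%, 11 within 50 bp and 9 to 12 in single replicates. Less frequent ones numbered 1 in the conservative list, 1 in the replicated list, 1 in the stronger 50%, 5 against flanks, 2 among single-copy peaks and 1 to 2 in single replicates. Odds ratios turned direction against flanks, which were not matched on GC content, for TAATTA (0.532), MEF2 (0.347), SOX (0.877) and FOX (0.695). They did so in the stronger 50% for TFAP2 (0.895) and CAGATG (0.896), in replicate 2 alone for AP-1 (0.9503, against 1.15 in replicate 1), and in single replicates for CAGATG (0.951 to 0.975). MEF2 missed the threshold in the series list (1.54). It newly passed as more frequent in the conservative list (3.32), the replicated list (1.67), replicate 2 alone (4.16), single-copy peaks (2.35) and against the reversed consensus (1.93).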

Other observations

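The comparison of promoter motifs, the search for mitochondrial matches at the summit, the limit on the share of peaks with copies and the chance test of the motif spacing were chosen only after the result was seen.

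In promoter peaks, against the reversed consensus in the same windows, 13 of 27 motifs were more frequent and 1 was less frequent by Fisher's exact test. Here, and for the reversed consensus in distal peaks, the test treated both searches as separate groups of windows and ignored their pairing. A reversed consensus keeps the bases of a motif but not the order of neighbouring bases, which was not accounted for. NF-Y was matched in 11.4% of 9867 promoter peaks against 0.831% (odds ratio 15.3), ETS factors in 7.58% against 0.689% (11.7) and the E-box CAGCTG in 10.2% against 1.42% (7.90). YY1, found at start sites of many common genes, stood in 185 peaks against 3 (54.0), and NRF1 in 180 against 1 (123). GRHL, an epithelial factor, was the motif below, in 10 peaks against 57 (0.182). These ratios depend on the background: in distal peaks CAGCTG stood at 39.4 and POU at 32.1 against the reversed consensus, and at 1.62 and 3.68 against GC-matched windows. GRHL stood at 0.575 and 3.81 there, and promoter peaks were not compared with GC-matched windows. GC content was 66.5% ± 7.55 (SD) around promoter summits and 57.4% ± 8.18 around distal ones, against 41.4% in windows outside peaks.

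The 10 strongest peaks of all were distal. Among the strongest 5% of distal peaks by signal (166 peaks), 12.05% had another near-identical copy over 80% of the peak in the assembly (7.94 to 17.9). The share was 8.19% of the other distal peaks (7.29 to 9.20). For most of the 166 no copy of this extent was found in the assembly, which argues against reads shared between such copies there. Copies of a shorter stretch, such as one under the summit, were not searched in the assembly and are not excluded. Copies that the assembly lacks cannot be found by this search, and sequences repeated very often may be missed by it, so these are not excluded either. Whether shared reads raised the 20 with a copy cannot be told apart from other sources, because the intervals overlap. A match to the mitochondrial genome over 80% of the peak held for 3.61% of the 166, which excludes it for most of them. Summits inside a match of at least 50 bp at 80% identity made up 4.82% (8 of 166) against 0.127% (4 of 3149). Matches were kept only up to a blastn expect value of 1e-10. Such summits made up 6 of the 10 strongest, 4 of which matched over 80% of the peak. Reads from mitochondrial DNA may account for the 8 among the 166. Weaker matches, and those beside the summit over less than 80% of the peak, were not counted. Mitochondrial reads are therefore not excluded for the remainder. No biological explanation was tested.

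The facial mesenchyme and clefting lists, like most lists, had more promoters open in the looser list than past IDR, and epithelial and neuronal genes went from 14 to 8 each and regulators of other organs from 16 to 6. Of the 62 facial mesenchyme and clefting genes with a promoter peak in the looser list, 39 passed IDR (62.9%, 50.5 to 73.8), against 79.7% of other genes, a difference for which the lists were chosen, so that no test of it decides anything, and their median signal was 4.19 against 6.92. Random genes matched on GC content passed at 79.9% (69.4 to 88.7), a range above the share of the lists, and unmatched random genes at 79.6%. Mean GC content was 64.7% at the promoter peaks of the lists and 63.4% at those of other genes. Matching on it therefore changed little and left the gap as it was. Random genes matched on signal passed at 53.1% (45.2 to 61.3), below the lists. The bound set beforehand counted a share outside this range against low signal, which was wrong for a share above it because passing IDR itself depends on peak strength, so low signal cannot be told apart from other sources. No biological explanation was tested.

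In distal peaks of the looser list the E-box CAGATG and the homeodomain core ATTA stood 6 bp apart 30 times, against a mean of 7.15 at the other gaps up to 30 bp and 8 in matched background windows. The adjusted Poisson p over 62 gaps and strands was 1.0e-08, which argues against chance, and 8 of the 30 pairs lay in peaks of the series list, which are no separate evidence. The share of pairs on repeat bases was 0% (upper limit 11.4%), against copies of a repeat family. The gap was the most frequent in each replicate's own looser list, with 13 and 17 pairs, so that neither replicate alone gave the gap its rank. These lists overlapped each other at 64.9% and 67.9% of their peaks, and the replicated list held peaks found in both replicates. Their counts are therefore no separate evidence for the spacing. A joint site of a bHLH factor such as Twist1 and a homeodomain factor is a hypothesis that may account for the spacing, found and tested on the same data, and binding was not measured. Sites lay for example near Nr5a2 on chromosome 1 at 137332579 to 137332594 and near App on chromosome 16 at 85128533 to 85128548, and none of the 30 had its nearest gene in the facial mesenchyme or clefting lists.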
